A study of Mus musculus with 9 samples.

How the data were processed

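Crypts were isolated from the small intestine and 2 ng of their RNA went into each Smart-seq2 library, per the labels' protocols. Smart-seq2 copies full-length polyadenylated transcripts and does not mark the strand, so reads from overlapping genes on opposite strands cannot be told apart. The authors deposited a table of read counts per gene for each of the 9 libraries, and these deposited counts are whole numbers that were not normalized. Per the submitters' processing notes, STAR 2.7, featureCounts and DESeq2 1.20 were used with the mm10 or GRCm38 build; the role of each, the annotation and the strand setting are not given in the sources used here. All row names (100%) were gene names of the GENCODE M21 annotation of GRCm38, from which coordinates and overlapping exons were taken. The labels conflict on the interval after induction (15 or 7 days), and 1 description line of the Villin samples names BNF where their titles name tamoxifen. Groups followed the driver and genotype in the titles.

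Counts for 55341 genes were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups, which left 16250, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 9 libraries (5 residual degrees of freedom, 7.43 prior degrees of freedom, biological coefficient of variation 0.332), so that all groups share an estimate of the spread. The contrasts were the mean of the KO effects of both drivers, which is the main comparison, the KO effect in each driver, the difference of the KO effects (AhCre minus Villin), and AhCre WT minus Villin WT. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. CPM are counts scaled by library size and TMM factor. All log2 fold changes are on the edgeR scale.

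The groups, contrasts, gene lists, named-gene rule and most alternatives were fixed before the data were examined. The 21 lists were tuft cell, goblet cell, Paneth cell, enteroendocrine cell, crypt base stem cell, proliferation, absorptive enterocyte, Notch pathway and secretory fate, germline, PRC1 subunits other than PCGF6, Polycomb-repressed developmental regulators, type 2 cytokine response, interferon and MHC class II, antimicrobial and regenerating-family, fetal-like and injury, aryl hydrocarbon receptor targets, lymphocyte and plasma cell, myeloid and mast cell, stromal (with muscle, endothelial and glial cell), dissociation and heat-shock stress, and mitochondrially encoded genes. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and with a correlation estimated from the data, adjusted over the 21 lists of a contrast. Camera compares a list with all other genes, so its direction can go against the sign of a list's median. Over all genes the median log2 fold change was -0.095 on average, -0.18 in Villin, -0.0048 in AhCre and 0.18 for the difference. Of the 84 list tests 35 were called with the preset and 0 with the estimated correlation. Named were Pcgf6, the 12 largest rises and 12 largest falls on average among called genes with no overlap between KO and WT libraries within each driver and a mean of at least 1 CPM, the 8 largest rises and falls in each driver by the same rule, the 5 smallest adjusted p for the difference and for the WT groups, up to 12 called members of the tuft cell and germline lists, and up to 4 called members of other lists or 2 members of a list with none. Symbols of the form Gm plus digits or ending in Rik were passed over. Further members of the fixed lists given as examples were chosen after their values were seen.

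For a gene without counts in a group, the bound was computed against 3 counts over the group, and for 1 to 3 counts a ratio with an exact 95% interval is given. The floor of 3 counts was 0.194 to 0.615 CPM in a single library.

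Alternatives were DESeq2 size factors, no low-count filter, a filter of at least 1 CPM in at least 4 libraries, the DESeq2 1.42.0 Wald test, limma-voom with sample weights, fits of 1 driver each, additive driver and genotype terms, a replicate block, a log2 fold change of at least 1 and each library left out, for which list members were recounted in 8 of the lists. Chosen after seeing the data were a block with crossed replicate numbers in AhCre, leaving out both Villin WT 2 and Villin KO 1, all alternatives for the WT groups, the left-out libraries for the correlation and the type 2 list, the tuft cell list in fits of 1 driver each, the overlap of calls between those fits and at an unadjusted p under 0.01, and a mean of the separate fits with a separate spread per driver. The last was first left out once its count had been seen, because its z test ignores the error of the spread, and was then put back. Lists of clock genes, leukocyte genes and NRF2-associated genes were also written after results had been seen, and some of the tests in the closing part were written or rewritten at that stage.

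The procedure was tested on simulated data with the real means and library sizes and 200 genes changed, assuming the same spread for both drivers. For the average over both drivers (15170 genes) it recovered 26% of 2-fold and 89% of 4-fold changes with 6.50% of calls false. For Villin (15113 genes) these were 4%, 67% and 2.74%, and for AhCre (15154 genes) 2%, 53% and 1.79%. The real spread was not equal, with a biological coefficient of variation of 0.423 in Villin alone and 0.133 in AhCre alone. The simulated rates are therefore not the error rates or the power of the real calls.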

Results

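Gene expression was measured by RNA sequencing of crypts isolated from the small intestine of male C57BL/6 mice aged 8 to 12 weeks. PCGF6 is a subunit of a variant Polycomb repressive complex 1, and the series asks what its loss changes in adult intestinal epithelial cells. Deletion was induced with either of 2 Cre drivers: AhCre, which is switched on by beta-naphthoflavone (BNF), and Villin-CreERT2, which is active in the intestinal epithelium and switched on by tamoxifen. The 9 libraries fell into 4 groups: AhCre wild type (WT, n = 2), AhCre Pcgf6 knockout (KO, n = 2), Villin WT (n = 3) and Villin KO (n = 2). The labels give 15 days after induction in their titles but 7 days in a second description line and in the design text, so the interval is uncertain. Total counts were 12377921 and 10645569 in AhCre WT, 10179884 and 9263993 in AhCre KO, 6535579, 7013456 and 6455098 in Villin WT, and 7146764 and 8339149 in Villin KO. The AhCre libraries had counts in 33791 to 38835 genes and the Villin libraries in 22058 to 29750. Replicates of AhCre differed less from each other than those of Villin, with a chi-square per degree of freedom of 8.45 and 13.0 in AhCre and 50.2 to 74.9 in Villin, so no pair was alike to within the counting error of reads, which leaves out the error of library preparation. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

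Pcgf6 itself (chromosome 19, 47033617 to 47050906, GRCm38) was lower in both KO groups but was not lost. Its counts were 219 and 136 in AhCre WT against 89 and 68 in AhCre KO, and 60, 99 and 49 in Villin WT against 15 and 16 in Villin KO. In CPM (counts scaled to library size) these were 14.1 and 10.1 against 7.20 and 5.90, and 10.8, 12.7 and 9.44 against 3.07 and 2.47. No library went against its genotype label. On average over both drivers Pcgf6 fell by 1.44 on the log2 scale (SE 0.29, adjusted p = 0.0327), and in Villin it fell by 1.99 (SE 0.42, adjusted p = 0.0220). In AhCre the change was -0.89 (SE 0.40, adjusted p = 1.0), but it passed by voom (0.0391) and in the AhCre libraries alone (0.0349). The Villin call was lost by voom (0.214) and in the Villin libraries alone (0.136). It was also lost with a replicate block (0.0560) and with crossed replicate numbers in AhCre (0.0773). The test of a difference between drivers did not pass (1.10, adjusted p = 0.356). Over the alternatives that keep all libraries the adjusted p of the average ranged from 0.00151 to 0.126. The call on the average was also lost without AhCre WT 1 (adjusted p = 0.255), AhCre WT 2 (0.153), AhCre KO 1 (0.159), AhCre KO 2 (0.214), Villin WT 1 (0.0758), Villin WT 2 (0.0796) or Villin KO 1 (0.0638). The Villin call was lost without AhCre WT 1 (0.0550), AhCre WT 2 (0.0526), Villin WT 1 (0.0513) or Villin KO 1 (0.0748), while the log2 fold change stayed between -2.13 and -1.76. Whether the counted exons include the deleted part of the gene is not stated in the labels.

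The main comparison asked which genes changed with the loss of Pcgf6 on average over both drivers. Of the gene lists, that of tuft cells, the chemosensory cells of the epithelium, had the most called members and the highest median. Of 42 tested members of the tuft cell list, 35 rose, 0 fell and 7 did not pass the test (40 rose adjusted over the list alone), and the median log2 fold change of the list was 3.14. Avil, an actin-binding protein of tuft cells, rose by 3.71 (SE 0.45, adjusted p = 0.00614), from 20.4 ± 2.24 to 117 ± 12.5 CPM in AhCre (SD, n = 2 and 2) and from 9.04 ± 3.08 to 270 ± 272 CPM in Villin (SD, n = 3 and 2). Chat, the enzyme that makes acetylcholine, rose by 3.18 (SE 0.41), and Slc18a3, the acetylcholine transporter encoded within the Chat locus, rose by 4.59 (SE 0.88, adjusted p = 0.0280). Slc18a3 had 1 count over AhCre WT and 46 over AhCre KO, a ratio of 55.6 (95% interval 9.50 to 2244, counting error only), and 3 and 25 in Villin, a ratio of 13.6 (4.15 to 70.4). Alox5 and Alox5ap, which start leukotriene synthesis, rose by 3.85 and 3.43, and Sucnr1, the succinate receptor, by 4.39. The tuft cell transcription factors Pou2f3 (3.29) and Gfi1b (3.71), the cation channel Trpm5 (3.28), the kinase Dclk1 (2.86) and the cytokine Il25 (4.39) also rose. Bmx, Matk, Sh2d6, Sh2d7, Lrmp and Strip2 rose by 3.13 to 3.44 on the log2 scale. Values for members that did not pass included Il17rb at 1.83 (adjusted p = 0.0758) and Tas1r3 at -0.35 (adjusted p = 0.757).

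The tuft cell list was called by camera with its preset correlation of 0.01 (adjusted p = 3.00e-89). The correlation estimated from the data was 0.872, and with it the call was lost (adjusted p = 0.0757 with an estimated correlation). No member was found to differ in its KO effect between drivers by the edgeR test (0 called, 5 lower and 0 higher at an unadjusted p under 0.05, and 0 by DESeq2 and by voom). Villin KO 1 stood apart, with a mean log2 CPM of the list of 6.67 against 4.22 in Villin KO 2 and 2.23 to 2.88 in Villin WT, whereas both AhCre KO libraries were close together at 5.02 and 5.06 against 2.89 and 2.95 in AhCre WT. The count of 35 dropped to 0 without AhCre WT 1 and without AhCre WT 2, to 1 without Villin WT 1 and to 21 without Villin WT 2, with list medians of 3.08, 3.11, 3.14 and 3.13. Without Villin KO 1 the count was 27 and the median 2.03.

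**Figure D1:**
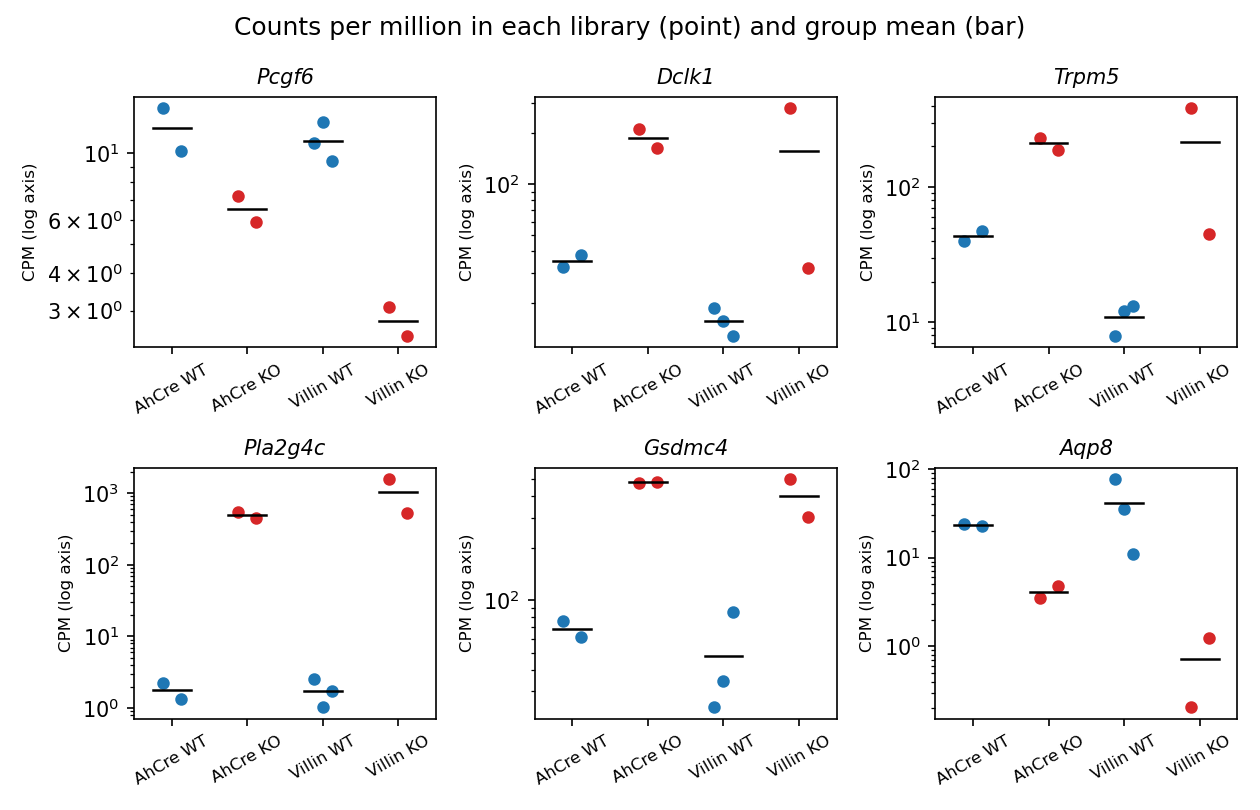
CPM on log axes for Pcgf6, the tuft cell genes Dclk1 and Trpm5, and Pla2g4c, Gsdmc4 and Aqp8, with 1 point per library and a bar at each group mean (n = 2, 2, 3 and 2 for AhCre WT, AhCre KO, Villin WT and Villin KO). Pla2g4c was at 443.5 CPM or more in every KO library and at 2.52 CPM or less in every WT library.

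Genes of the epithelial response to type 2 cytokines also rose on average. Pla2g4c, a cytosolic phospholipase A2 (chromosome 7, 13324655 to 13360672, GRCm38), had the smallest adjusted p of all genes tested and rose by 8.66 (SE 0.47, adjusted p = 3.76e-06), with counts of 35 and 18 in AhCre WT against 6671 and 5114 in AhCre KO and of 14, 8 and 9 in Villin WT against 7654 and 3427 in Villin KO. Of 16 tested members of the type 2 list, 7 rose and 9 did not pass the test (10 rose and 1 fell adjusted over the list alone), with a median of 1.08. Besides Pla2g4c these were Gsdmc2, Gsdmc3 and Gsdmc4 of the gasdermin C family (2.87, 2.75 and 2.93), Sprr2a3 (3.35), the alarmin Il33 (1.40) and the goblet cell protein Retnlb (4.84). Il33 was at 0.03 in AhCre (adjusted p = 1.0), where KO and WT libraries overlapped, and at 2.77 in Villin. The gasdermin C and Sprr2a genes are near-identical copies, so their separate values are uncertain. Retnlb had 3 counts over AhCre WT and 156 over AhCre KO, a ratio of 62.9 (95% counting interval 21.1 to 308). The camera call of this list (adjusted p = 1.46e-22) was lost with an estimated correlation (adjusted p = 0.0586 with an estimated correlation). The count of 7 dropped to 1 without AhCre WT 1 or AhCre WT 2 and to 2 without Villin WT 1.

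Genes outside these lists that rose included Itprid1 (3.90), Vmn2r26, a vomeronasal receptor (4.29), U90926 (3.72), and Duox2 and its maturation factor Duoxa2, which produce hydrogen peroxide at the epithelial surface (3.03 and 3.38). Tdrkh, a piRNA pathway gene, was the member of the germline list that rose, by 2.81 (SE 0.51, adjusted p = 0.0208), and 14 of 15 tested members did not pass. Its call was lost without any of the 4 AhCre libraries or Villin WT 1. The other 40 listed germline genes had too few counts to be tested. Calhm3, an ion channel subunit gene that lies close to Pcgf6 (chromosome 19, 47151609 to 47157764), rose by 4.91 (adjusted p = 0.0429). With 0 counts over Villin WT and 21 over Villin KO it was at least 11.4-fold higher in Villin KO. Genes that fell included the water channel Aqp8, by 4.11 (SE 0.57, adjusted p = 0.00614), the phosphate transporter Slc34a2, by 1.79 (SE 0.26), the iron exporter Slc40a1 (-1.82), the tight junction gene Cldn8 (-2.73), Insc (-1.61), Ankrd26 (-1.71), Whrn (-2.04), Igdcc4 (-2.39) and the DNA repair gene Fancd2 (-1.79). Egf (-3.70) and Nkx6-3 (-4.34) also fell, and with 0 counts over Villin KO they were at least 3.88-fold and 9.60-fold lower there. All these falls were negative in both drivers but smaller in AhCre, and several lay mainly in Villin. Slc34a2 was at -3.05 in Villin and -0.53 in AhCre, Ankrd26 at -2.81 and -0.60, Whrn at -3.38 and -0.71, and Fancd2 at -3.15 and -0.42. By contrast, Aqp8 was at -5.71 and -2.50 and Slc40a1 at -2.16 and -1.48. Cldn8 had 74 counts over Villin WT and 2 over Villin KO, a ratio of 0.0441 (95% interval 0.00525 to 0.165), and Igdcc4 28 and 1, a ratio of 0.0583 (0.00143 to 0.353). The floor behind each bound was 3 counts over the group, and floors and intervals cover counting error only. Avil, Alox5ap, Sh2d7, Lrmp, Duoxa2, Tdrkh, Fancd2 and Egf share exon positions with other genes, and because Smart-seq2 does not keep the strand their values are uncertain.

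In all, 190 of 16250 genes tested changed on average, 158 higher and 32 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The KO libraries lay beyond all WT libraries in the same direction in both drivers for 173 of them, where chance gives 3.33% of genes, although genes were called on these same values. Of the 190, 158 were higher and 30 lower in both drivers by fitted fold change, and 2 had opposite signs. Genes were called on the mean of both effects, so a large value in Villin could carry a call. Il33, at 2.77 in Villin and 0.03 in AhCre, counts among those higher in both. An equal sign thus does not show a change in each driver. DESeq2 called 438 and no low-count filter 538. The count was 2 without AhCre WT 1, 2 without AhCre WT 2, 72 without AhCre KO 1, 77 without AhCre KO 2, 12 without Villin WT 1, 87 without Villin WT 2, 95 without Villin KO 1 and 757 without Villin KO 2.

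Among the remaining lists on average, the crypt base stem cell list had 28 of 31 and the proliferation list 36 of 36 members at negative values, with medians of -0.35 (-0.69 without Villin KO 2) and -0.49 (-0.19 without Villin KO 1 and -1.06 without Villin KO 2). None of their members passed the edgeR test (8 lower in each and 0 higher at an unadjusted p under 0.05, 0 stem cell genes and 1 proliferation gene by DESeq2, 0 in each by voom). Both lists were called lower by camera (adjusted p = 0.00267 and 8.16e-07) and neither with an estimated correlation (adjusted p = 0.491 and 0.538 with an estimated correlation). The absorptive enterocyte list had a median of 0.29 (0.20 without Villin KO 1) with 0 members called (9 rose adjusted over the list alone, 12 higher at an unadjusted p under 0.05, 7 rose by DESeq2 and 7 by voom), and its camera call (5.09e-08) was lost (adjusted p = 0.229 with an estimated correlation). The stromal list (median 0.47, with 1 of 20 members rising, the actin-severing gene Gsn at 1.42), the myeloid list (0.25, with 1 of 22 rising, the receptor Kit at 1.83) and the stress list (0.43, with 1 of 24 rising, Hspa1a at 2.82) were called higher by camera (adjusted p = 0.000257, 0.0228 and 0.000211), and none of these calls held (adjusted p = 0.225, 0.776 and 0.0757 with an estimated correlation). The myeloid median turned to -0.20 without Villin KO 2 and was 0.15 without AhCre WT 1, 0.16 without AhCre WT 2, 0.05 without Villin WT 2, 0.80 without Villin WT 3 and 0.47 without Villin KO 1. The stromal median was 1.15 without Villin WT 1 and the stress median 0.18 without Villin KO 1. In Villin the stromal and myeloid medians were 1.29 and 1.32, but in AhCre -0.58 and -0.50, so their averages combine opposite changes. Hspa1a had 2 counts over Villin WT and 22 over Villin KO, a ratio of 18.0 (95% interval 4.41 to 158, counting error only). The calls of Gsn, Kit and Hspa1a were lost without AhCre WT 1, AhCre WT 2, AhCre KO 1, AhCre KO 2, Villin WT 1, Villin WT 2 or Villin KO 1. Without Villin KO 2 the calls were 3 lower stem cell, 17 lower proliferation, 5 higher and 1 lower enterocyte, 6 higher stress, 3 higher fetal-like and 1 higher aryl hydrocarbon receptor gene. The camera call was lost too for the fetal-like list (median 0.31, 0.77 without Villin WT 1; 0.00369, then adjusted p = 0.215 with an estimated correlation) and the aryl hydrocarbon receptor list (median 0.46, 0.31 without AhCre KO 1 and 0.21 without Villin KO 1; 0.0286, then 0.215), which had 4 and 3 members higher at an unadjusted p under 0.05, none called by edgeR, 2 and 0 by DESeq2, and 1 and 0 by voom.

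Camera called none of the other lists on average. The goblet list had 2 of 26 members rising (3 adjusted over the list alone), St3gal6 and Atp2a3 at 1.13 and 1.96, with a median of -0.02, a mean of 0.12 and camera's direction upward. Both goblet calls were lost without any 1 library except Villin KO 2, where 3 rose. Duox2 and Duoxa2 were the 2 of 16 antimicrobial genes that rose (2 rose and 1 fell adjusted over the list alone), against a median of -0.35 and a mean of 0.11. Both were lost without AhCre WT 1, AhCre WT 2 or Villin WT 1 and 1 of them without AhCre KO 1 or Villin WT 2. Without Villin KO 2 the list had 3 lower members besides 2 higher. The Paneth list had a median of -0.19 and a mean of -0.03 and the interferon list -0.18 and -0.09, both with camera pointing upward. Medians were -0.19 in the enteroendocrine list, -0.12 in the Notch list, -0.11 in the list of other PRC1 subunits, 0.12 in the Polycomb-repressed regulators, 0.07 in the lymphocyte list and -0.01 in the mitochondrially encoded list, which camera pointed upward against a mean of -0.04. The edgeR test called 0 members in each of these 8 lists, with 1 Paneth gene rising and 1 enteroendocrine gene falling adjusted over the list alone. The Paneth list had 1 member higher and 2 lower without Villin KO 2 (median -1.17) and 2 higher without Villin WT 3 (median 0.27), and its median was also positive without Villin KO 1 (0.23). The interferon list had 1 member higher and 7 lower without Villin KO 2. At an unadjusted p under 0.05 the counts higher and lower were 3 and 1 for Paneth, 1 and 4 for enteroendocrine, 2 and 2 for interferon, 0 and 1 for Notch, 1 and 3 for PRC1, 0 and 0 for Polycomb-repressed regulators, 0 and 1 for lymphocyte and 0 and 1 for mitochondrial genes. DESeq2 and voom each called 1 enteroendocrine gene as lower, voom called 2 Paneth genes as higher, and neither called another member of these 8 lists. Of 68 listed developmental regulators only 10 had enough counts to be tested, so a small change of the others from near 0 counts was not detectable.

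**Figure D2:**
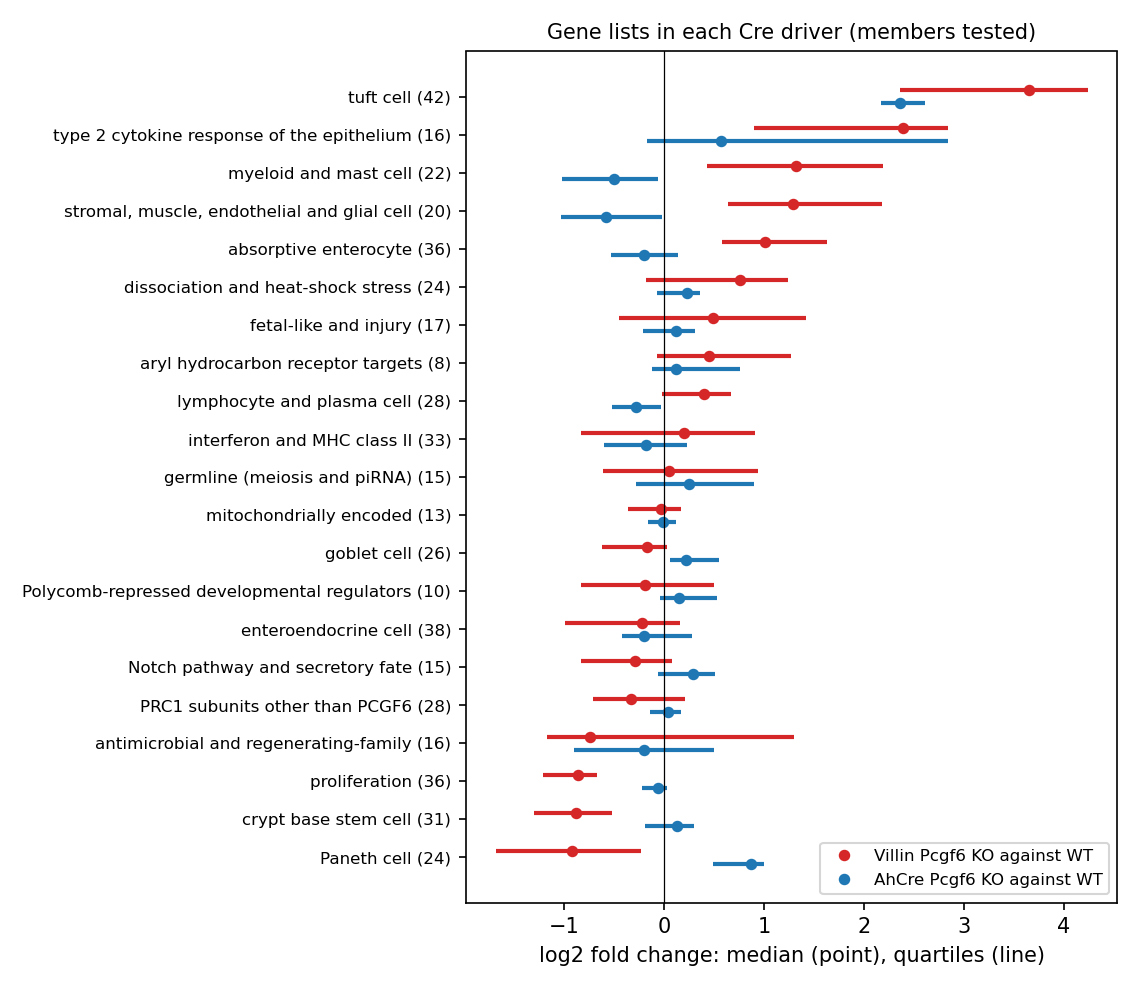
Median log2 fold change (point) and quartiles (line) of the members tested in each of 21 gene lists, for Villin KO against WT in red and AhCre KO against WT in blue. The tuft cell list had the highest median in both drivers, 3.65 in Villin and 2.36 in AhCre.

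In Villin KO against Villin WT, genes of absorptive enterocytes rose along with the tuft cell and type 2 genes. Of 36 tested enterocyte genes 16 rose and 20 did not pass (20 rose adjusted over the list alone), with a median of 1.01. They included the sugar transporters Slc2a5 for fructose (2.94, SE 0.36, adjusted p = 0.00482), Slc5a1 (2.44) and Slc2a2 (1.96) for glucose, and the peptide transporter Slc15a1 (1.84), along with brush border enzymes such as Alpi (1.63), Dpp4 (1.64) and Sis (1.34). Of 31 stem cell genes 4 fell (7 fell and 1 rose adjusted over the list alone), namely Lrig1 (-1.82), Slc12a2 (-2.06), Axin2 (-1.41) and the stem cell receptor Lgr5 (-1.40), with a list median of -0.88 (-0.55 without Villin WT 2 and -1.57 without Villin KO 2). Of 36 proliferation genes 3 fell (3 adjusted over the list alone), Mki67 (-2.16, SE 0.39, adjusted p = 0.0131), Cenpf (-2.52) and Cenpe (-2.02), all 36 had negative values, and the median was -0.86 (-0.26 without Villin KO 1 and -2.15 without Villin KO 2). Collagens and other stromal genes rose at the same time, 5 of 20 (8 adjusted over the list alone) with a median of 1.29 (2.53 without Villin WT 1), including Col1a1 (3.39) and Col3a1 (2.78). Of 22 myeloid genes Kit rose (2.20; 7 rose and 1 fell adjusted over the list alone), with a median of 1.32 (2.36 without Villin WT 3 and 0.35 without Villin KO 2). Of 24 stress genes 5 rose (7 adjusted over the list alone), including Fos (2.18), with a median of 0.76 (0.24 without Villin KO 1). Villin KO 1 and Villin WT 2 stood apart from the rest of their groups in cell type genes. The mean log2 CPM of the proliferation list was 3.85 in Villin KO 1 against 5.52 in Villin KO 2 and 5.56 to 6.05 in Villin WT, and that of the Paneth list was 4.79 in Villin KO 1 and 5.07 in Villin WT 2 against 7.12 to 7.95 in the other Villin libraries. The enterocyte mean was 10.8 and 10.5 in Villin KO against 9.38 to 9.95 in Villin WT.

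The enterocyte, stem cell, proliferation, stromal, myeloid and stress calls of camera in Villin (adjusted p = 5.16e-16, 0.000163, 6.73e-08, 1.38e-08, 5.32e-05 and 0.000795) were all lost with an estimated correlation (adjusted p = 0.141, 0.380, 0.451, 0.140, 0.440 and 0.140 with an estimated correlation). By voom 5 enterocyte, 0 stem cell, 0 proliferation and 1 stress gene were called, and with the Villin libraries fitted alone 4, 0, 1 and 1. The 16 enterocyte calls became 4 without AhCre KO 1, AhCre KO 2 or Villin WT 1, 7 without AhCre WT 1, 5 without AhCre WT 2 and 1 without Villin KO 1, where the median was 0.79. The stem cell and proliferation calls dropped to 0 and 0 without Villin KO 1, where the medians were -0.66 and -0.26, and to 0 and 0 without Villin WT 1, and rose to 13 and 25 without Villin KO 2. The 4 stem cell calls became 2 without AhCre WT 1, AhCre WT 2, AhCre KO 1, AhCre KO 2 or Villin WT 2 and 8 without Villin WT 3. The 3 proliferation calls became 1 without Villin WT 2. The 5 stromal calls became 1 without Villin KO 1. The myeloid call of Kit was lost without AhCre WT 2, AhCre KO 1, AhCre KO 2 or Villin WT 1, with 5 myeloid calls without Villin WT 3 and 2 without Villin KO 1. The 5 stress calls became 2 without any of the 4 AhCre libraries, 0 without Villin WT 1 or Villin KO 1, 3 without Villin WT 2 or Villin WT 3. They became 10 higher and 1 lower without Villin KO 2.

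Tuft cell genes rose in Villin as well, 36 of 42 (40 adjusted over the list alone) with a median of 3.65, and so did 7 of 16 type 2 genes (13 adjusted over the list alone) with a median of 2.40, including Pla2g4c (9.24), Il33 (2.77), Sprr2a3 (4.16) and Socs3 (1.67). The camera calls of both lists (adjusted p = 1.94e-41 and 5.16e-16) were lost (adjusted p = 0.188 and 0.102 with an estimated correlation). The 36 tuft cell calls became 16 by voom, 39 by DESeq2 and 30 of 39 with the Villin libraries fitted alone. They became 9 without Villin KO 1, with a median of 1.85, and 5 without Villin WT 1. The 7 type 2 calls became 3 without Villin KO 1 or Villin WT 1. Villin genes without counts in 1 group included the prostaglandin synthase Ptgs2, at least 23.9-fold higher in KO, the guidance gene Sema5b, at least 14.1-fold higher, and Brsk2, Ttc6, Zfp618, Zfand4 and the enteroendocrine transcription factor Nkx2-2, at least 7.56-fold, 8.99-fold, 5.92-fold, 6.13-fold and 2.86-fold lower. Fkbp10 and Prss53 each had 1 count over Villin WT against 27 and 36 over Villin KO, ratios of 44.1 (95% interval 7.26 to 1804) and 58.8 (9.89 to 2385). Nkx2-2 was the 1 of 38 enteroendocrine genes that fell (0 adjusted over the list alone), and Jag2, a Notch ligand, the 1 of 15 Notch genes that fell (1 adjusted over the list alone), with 32 counts over Villin WT and 1 over Villin KO, a ratio of 0.0510 (95% interval 0.00125 to 0.305). The call of Nkx2-2 was lost without any 1 library. Without Villin WT 3, 1 Notch gene rose and 2 fell, and no Notch call was left without any other single library. Brsk2, Ttc6, Nkx2-2, Prss53 and Fkbp10 overlap exons of other genes and are uncertain for that reason.

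In the remaining lists in Villin, 4 of 26 goblet genes rose (4 rose and 2 fell adjusted over the list alone), including the secreted protein Clca1 (1.90), while the list median was -0.18, the mean -0.06 and camera's direction upward. Antimicrobial genes went both ways, with Duox2 (3.66), Duoxa2 (3.95) and the calprotectin subunit S100a9 (4.43) rising and Nos2 (-2.50) falling (4 rose and 2 fell adjusted over the list alone). That list had a median of -0.74 and a mean of 0.20. Of 33 interferon and MHC class II genes Usp18 rose (2.29) and Ciita, the regulator of MHC class II, fell (-2.40), with 6 rising and 6 falling adjusted over the list alone, a median of 0.20 and a mean of -0.06. Emp1 (1.78) and Areg (2.67) were the 2 of 17 fetal-like genes that rose (3 adjusted over the list alone), and the camera call (0.00544) was lost (adjusted p = 0.189 with an estimated correlation). Cyp1a1 (2.39) was the 1 of 8 aryl hydrocarbon receptor targets that rose (1 adjusted over the list alone), and Tdrkh (2.66) the 1 of 15 germline genes (2 adjusted over the list alone). With each library left out, 0 to 4 goblet genes rose, 1 to 2 antimicrobial genes rose and 0 to 4 fell, and 0 to 7 interferon genes rose and 0 to 7 fell. In the same way 0 to 3 fetal-like, 0 to 2 aryl hydrocarbon receptor and 0 to 2 germline genes rose. The most were called without Villin WT 3 or Villin KO 2. The fetal-like median of 0.49 was 0.89 without Villin WT 1 and 0.31 without Villin KO 2. The Paneth list had a median of -0.92 with 0 called (2 higher and 4 lower at an unadjusted p under 0.05, 1 rose by DESeq2 and 1 by voom). Without Villin KO 2, 10 Paneth genes fell and 1 rose with a median of -3.20, without Villin WT 3, 2 rose with a median of -0.06, and without Villin KO 1 the median was -0.30. The PRC1 subunits (median -0.33), the Polycomb-repressed regulators (-0.19, with a mean of -0.22 and camera's direction upward), the lymphocyte list (0.40) and the mitochondrially encoded list (-0.03) had 0 called by edgeR. At an unadjusted p under 0.05 they had 2 higher and 5 lower, 0 and 0, 0 and 1, and 0 and 1, and the only calls by DESeq2 or voom were 1 PRC1 gene rising and 1 falling by DESeq2.

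In total 1009 genes changed in Villin, 541 higher and 468 lower, and with DESeq2 size factors the split was 704 higher and 388 lower of 1092, a shift of all log2 fold changes by 0.11. The count was 258 when the Villin libraries were fitted alone (223 higher and 35 lower), 138 by voom (132 and 6) and 1749 by DESeq2 (1097 and 652). It was 356 without AhCre WT 1, 343 without AhCre WT 2, 348 without AhCre KO 1, 349 without AhCre KO 2, 144 without Villin WT 1, 73 without Villin KO 1 and 1949 without Villin KO 2. Without both Villin WT 2 and Villin KO 1, a pair left out after their values were seen, it was 343.

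In AhCre KO against AhCre WT, Pla2g4c rose by 8.07 (SE 0.67, adjusted p = 0.000517) and was the 1 gene called. The tuft cell list had a median of 2.36 with 0 of 42 members called over all genes tested, 36 rising adjusted over the list alone, 36 higher at an unadjusted p under 0.05, 18 called by DESeq2 and 39 by voom. Fitted with the AhCre libraries alone, 38 of 41 tuft cell genes rose, among them Dclk1 (2.42, SE 0.18) and Pou2f3 (2.52). In that fit 14 of 24 Paneth genes rose, including the antimicrobial genes Ang4 (1.76) and Mptx2 (0.76) and the defensin-processing enzyme Mmp7 (0.70), and Spp1 fell. Enterocyte genes went both ways in it, with 5 of 36 rising and 9 falling, including the disaccharidases Sis (-0.72) and Lct (-0.97). There 8 of 20 stromal genes, led by Col1a1 (-1.98), and 7 of 21 myeloid genes, among them Lyz2 (-1.02), fell, and 1 of each rose, Gsn and Kit. Of 33 interferon and MHC class II genes 5 rose in it, among them H2-Aa (1.25) and Cd74 (0.66), 4 fell, among them Isg15 (-1.19) and Irf7 (-0.64). The others did not pass (median -0.16). In the fit of all libraries edgeR called 0 Paneth, enterocyte, stromal, myeloid and interferon genes, with 0 and 0, 0 and 4, 0 and 1, 1 and 2, and 0 and 1 members higher and lower at an unadjusted p under 0.05. There DESeq2 called 2 enterocyte genes and 1 stromal gene as lower and 0 in the other 3 lists. By voom the calls were 4 Paneth genes as higher, 2 enterocyte genes as higher and 6 as lower, 4 stromal genes as lower, 1 myeloid gene as higher and 3 as lower, and 1 interferon gene in each direction. The MHC class II and defensin genes belong to families of similar copies and are uncertain.

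In the fit of all libraries, 574 genes had an unadjusted p under 0.05 in AhCre, 294 higher and 280 lower. DESeq2 called 74, voom 911 and the fit of AhCre libraries alone 1049, 589 higher and 460 lower. The biological coefficient of variation was 0.133 in AhCre alone, 0.423 in Villin alone and 0.332 over all libraries. The shared estimate thus lay above the spread of AhCre and below that of Villin. The count of 1 became 4 without Villin WT 3, 53 without Villin KO 1, 64 without Villin KO 2 and 123 without both Villin WT 2 and Villin KO 1. The tuft cell count of 0 became 20 without Villin KO 1, 24 without Villin KO 2 and 29 without that pair.

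Camera called 7 lists in AhCre with the preset correlation: tuft cell (adjusted p = 3.23e-69), type 2 (1.54e-10, median 0.57), Paneth (1.84e-05, 22 of 24 members positive, median 0.87) and goblet (0.0105, median 0.22) upward, and enterocyte (0.0105, median -0.20), myeloid (0.0230, median -0.50) and stromal (0.0103, median -0.58) downward. None held with an estimated correlation (adjusted p = 0.153, 0.153, 0.646, 0.646, 0.646, 0.690 and 0.459 with an estimated correlation, in the same order). Of the type 2 genes 1 rose over all genes tested, Pla2g4c (6 rose and 1 fell adjusted over the list alone). For this list DESeq2 called 5 members as higher and 1 as lower, and voom 6 and 1. With the AhCre libraries fitted alone 6 of 14 type 2 genes rose and 2 fell, Arg1 and Ccl24. Adjusted over the list alone, Tdrkh of the germline list rose, 2 enterocyte genes and 1 stromal gene fell, and edgeR called 0 members of the other 16 lists (1 to 3 members at an unadjusted p under 0.05 in 12 of them). DESeq2 called 0 in these 16 lists, while voom called 1 to 5 members in 14 of them and the fit of the AhCre libraries alone members in 15. The calls by voom included 4 Paneth and 4 goblet genes as higher, 1 myeloid gene as higher and 3 as lower, and 2 stem cell genes in each direction. Medians of the lists not called lay between -0.28 and 0.28, with the lymphocyte list lowest and the Notch list highest. The antimicrobial list had a median of -0.20 with a mean of 0.02, and the mitochondrially encoded list -0.01 with 0.04, and camera pointed upward for both. The count of 1 type 2 gene became 3 without Villin WT 3 and 2 without Villin KO 2. The type 2 median was 0.18 without AhCre KO 1, 1.23 without AhCre KO 2 and 1.34 without AhCre WT 2. The goblet median was 0.13 without AhCre KO 2 and the stromal median -0.88 without AhCre KO 2 and -0.28 without Villin KO 1.

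**Figure D3:**
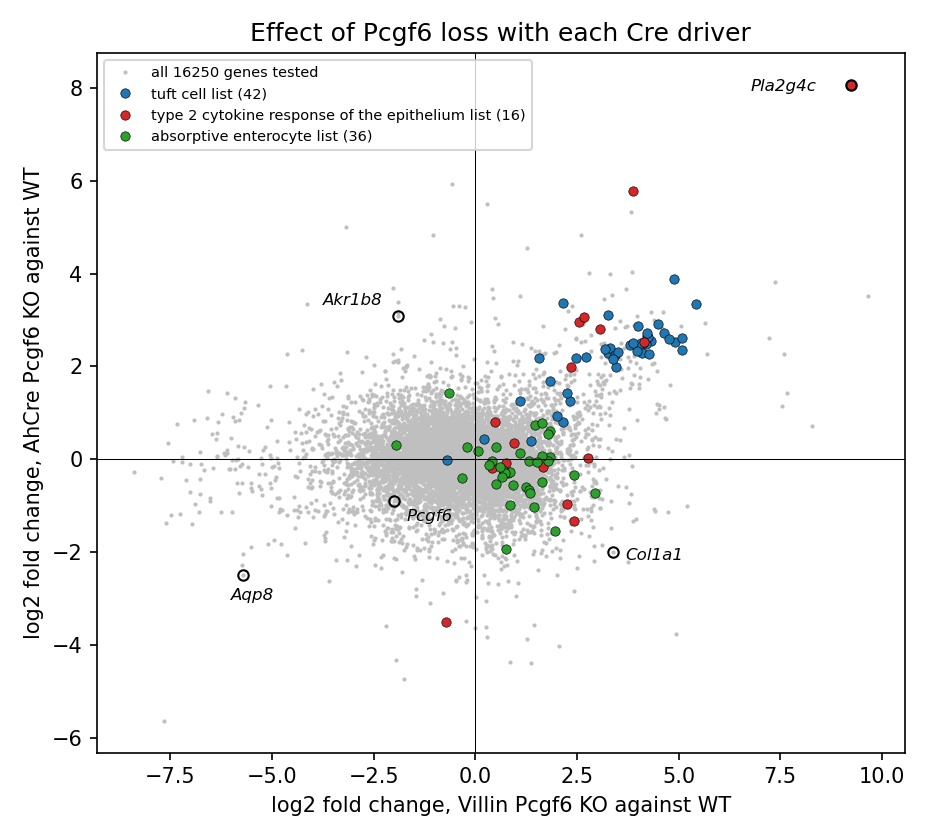
Log2 fold change of each of 16250 genes tested (grey points) in Villin KO against WT on the horizontal axis and in AhCre KO against WT on the vertical axis, with the tuft cell, type 2 and enterocyte lists in colour. Over all genes Pearson's r was 0.0909, while the tuft cell genes lay high on both axes.

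The drivers were then compared with each other. Across all 16250 genes, which are not independent replicates, the log2 fold changes of the drivers had a Pearson's r of 0.0909 and a Spearman's rho of -0.07, and r was 0.0228 to 0.103 with each library left out. Shared changes lay among the risers: at an unadjusted p under 0.01, 904 genes were higher in Villin and 117 in AhCre with 80 shared, where independent lists would share 6.51, and 1015 and 70 genes were lower with 4 shared, where independent lists would share 4.37. In fits of 1 driver each, which have no library in common, 218 Villin and 493 AhCre risers shared 115 genes against 8.09, and 27 and 381 genes that fell shared 2 against 0.775. The genes that fell in both fits were Aqp8 and Gm44223, the latter named after its value was seen. Both overlaps were chosen after the data were seen. Of the 541 genes that rose in Villin 57.1% had a positive value in AhCre, and of the 468 that fell 53.2% had a negative one.

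The test of the difference between the KO effects called 12 genes (adjusted p from 0.0346 to 0.0481), 11 lower and 1 higher in AhCre relative to Villin. Those named were the fructose transporter Slc2a5 (difference -3.67, SE 0.54), the glucose transporter Slc2a2 (-3.51), the sialic acid lyase Npl (-3.73), the collagen gene Col1a1 (-5.38), the dynein gene Dnah2 (-3.55) and the aldo-keto reductase Akr1b8 (5.0). Col1a1 was at 53.3 ± 8.11 CPM in AhCre WT against 13.4 ± 0.757 in AhCre KO, and at 1.45 ± 1.42 in Villin WT against 15.1 ± 1.35 in Villin KO (SD, n = 2, 2, 3 and 2). Akr1b8 went from 4.31 ± 1.03 to 37.0 ± 5.74 CPM in AhCre and from 16.3 ± 9.51 to 4.34 ± 0.629 CPM in Villin. Dnah2 overlaps an antisense gene and is uncertain. Camera called 9 of 21 lists for the difference and none with an estimated correlation, the smallest adjusted p being 0.2. In 3 lists camera pointed downward against a positive median: enteroendocrine (0.20, mean 0.33), germline (0.30, mean 0.27) and antimicrobial genes (0.53, mean -0.17). DESeq2 called 380 genes, voom 144 and the fit without a low-count filter 340. The count was 0 without AhCre WT 1, AhCre WT 2, AhCre KO 1, AhCre KO 2, Villin WT 2 or Villin KO 1, where 1354 to 3003 genes had an unadjusted p under 0.05, 415 without Villin KO 2, and 113 without both Villin WT 2 and Villin KO 1.

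Between the WT groups of the drivers, where driver, inducing compound and any batch are 1 factor, 1231 genes differed, 657 higher and 574 lower in AhCre WT. Col1a1 (5.21), the secreted Wnt antagonist Sfrp5 (4.30) and the transcriptional regulator Hcfc1 (2.41) were higher in AhCre WT, and the phosphatase Ptprr (-2.81) and the proteasome subunit Psmc1 (-2.61) were lower. Ptprr overlaps another gene and is uncertain. The share of counts in 11 satellite-like gene models was 0.0998% to 0.180% in AhCre and 0.000696% to 0.0111% in Villin libraries, and mitochondrially encoded genes took 2.07% to 3.04% and 3.41% to 4.92%. The count was 29 without AhCre WT 1, 8 without AhCre WT 2, 346 without AhCre KO 1, 365 without AhCre KO 2, 166 without Villin WT 1, 3030 without Villin WT 2, 597 without Villin WT 3, 2270 without Villin KO 1 and 2325 without Villin KO 2.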

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

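Of the tests in this part, those of leukocyte RNA, of a lower share of the main epithelial cell types, of type 2 signalling, of Villin KO 1 alone and of villus tissue were chosen or rewritten only after the results had been seen, and the clock lists were written after 4 clock output genes had been seen to rise.

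The KO effect differed between the drivers by the interaction test for 12 genes. Those named were Slc2a5 (-3.67), Npl (-3.73), Col1a1 (-5.38), Akr1b8 (5.0), Slc2a2 (-3.51) and Dnah2 (-3.55), as AhCre minus Villin on the log2 scale. The clock output genes Hlf (-5.46) and Bhlhe40 (-3.11) were also among the 12. Col1a1 is on the stromal list. The mean log2 CPM of that list was 3.14 and 3.05 in AhCre WT against 2.62 and 2.54 in AhCre KO. In Villin it was 2.33, 1.01 and 0.83 in WT against 3.11 and 2.86 in KO. The difference for Col1a1 need therefore not lie in epithelial cells, and its source was not tested. By camera with the preset correlation 9 lists differed as well, with median differences of -1.28 for tuft cell, 1.58 for Paneth cell, 1.03 for stem cell, 0.79 for proliferation, -1.16 for enterocyte, -0.72 for type 2, -1.50 for myeloid, -1.81 for stromal and -0.36 for stress genes. None of the 9 held with an estimated correlation, and 0 genes differed without Villin KO 1 by the edgeR test, where 2754 had an unadjusted p under 0.05.

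The rise of tuft cell genes was weighed first. Of the 60 splits of the libraries within the drivers, the real one included, only the real one called as many genes (190, highest other 12). It alone gave as high a tuft cell median (3.14, highest other 2.58). That other split kept the AhCre groups and exchanged Villin KO 2 for Villin WT 3. Most other splits mix KO and WT libraries, which adds any KO effect to the spread and lowers their number of calls. With the real split 1 of only 60, a chance split is argued against but not excluded. The highest median of 10000 random lists matched on expression, GC content and exon length was 0.555, below the tuft cell median in each driver; leukocyte-wide genes, of which 13 were tested and 4 belong to the myeloid list, had an upper quartile of -0.39 in AhCre and, with 13 of 13 positive, of 0.59 in Villin (tuft cell lower quartiles 2.17 and 2.36), and a lower share of the main cell types is argued against by the highest upper quartile of the goblet, Paneth and enteroendocrine lists in AhCre, 1.00. Type 2 cytokine signalling is known to expand tuft cells. It may have been set off by something the KO mice shared other than the loss of Pcgf6. The lower of the type 2 medians of the drivers was 0.57, in AhCre, where 10 of 16 members were positive and 6 negative. That median was 0.18 without AhCre KO 1, 1.23 without AhCre KO 2 and 1.34 without AhCre WT 2. These values cannot decide the question. Only RNA of the listed genes was measured, not the signalling itself, and a rise of the list does not tell its cause. The loss of Pcgf6 itself remains open beside such signalling as the biological explanation the groups name.

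The rise of enterocyte genes and fall of proliferation genes in Villin KO was weighed second. Villin KO 1 alone is argued against for the enterocyte genes, whose median without it was 0.79 with a lower quartile of 0.36. That value rests on Villin KO 2 as the 1 KO library left, so it does not show an effect of the group. For the proliferation genes Villin KO 1 alone cannot be told apart from an effect of the group. Their median without Villin KO 1 was -0.26 with an upper quartile of -0.11. More villus tissue in the Villin KO preparations cannot be told apart from other causes either: stem cell and Paneth genes, which it would lower as well, had medians of -0.88 and -0.92, but the Paneth median was -0.30 without Villin KO 1 and -0.056 without Villin WT 3. Villin KO 2 had a Paneth mean log2 CPM of 7.13, within the 5.07 to 7.95 of Villin WT. A change of differentiation with the loss of Pcgf6 was not tested and stays open.

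Clock output genes rose in Villin KO, with Ciart, Hlf, Usp2 and Bhlhe40 seen first (median 3.27). A candidate explanation is that KO and WT mice of the Villin line were taken at different times of day, since the evening arm of the clock (Dbp, Tef, Nr1d1, Nr1d2, Per1, Per2 and Per3; 7 of 7 rose, but with the Villin libraries fitted alone 2, Dbp and Per1) and the morning arm (Arntl, Npas2, Clock and Nfil3; Arntl fell) had medians of 1.71 and -0.78, a difference of 2.49, and 2.14 to 2.96 with each library left out. In AhCre the medians were -0.41 and -0.10, so a time difference of this kind would not cover the tuft cell genes there. The labels give no time of collection, and an effect of Pcgf6 on the clock in Villin stays open. Whether a time difference also bears on the enterocyte genes in Villin was not tested.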

How the results depend on the processing

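The test covered the 16250 genes with enough counts and had 5 residual degrees of freedom from 2 to 3 libraries per group. AhCre and Villin libraries differed in spread, while the test shares an estimate over both. The shared coefficient of variation (0.332) was below that of Villin alone (0.423) and above that of AhCre alone (0.133). By construction the shared test is therefore too lenient for Villin and too strict for AhCre. Fits of 1 driver each called 258 genes in Villin against 1009, and 1049 in AhCre against 1. Where a left-out library leaves a group with 1 library, that library is assumed to vary like the others. Causes of the moves below were not tested except where the construction shows them.

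With DESeq2 size factors, a stricter low-count filter or a log2 fold change of at least 1, all counts of calls stayed within 1.5 times of their first value (196, 163 and 189 for the 190 genes on average), as did 266 by voom and 133 with additive terms for these. Without a low-count filter the counts were 538 on average, 1591 in Villin, 137 in AhCre, 340 for the difference and 2290 between the WT groups, and by DESeq2 438, 1749, 74, 380 and 2278, with 188 of the 190 shared. By voom they were 138 in Villin, 911 in AhCre, 144 for the difference and 3860 between the WT groups. Fits of 1 driver each gave 258 in Villin and 1049 in AhCre, and a separate spread per driver, a z test that ignores the error of the spread, 731 on average with 165 of the 190 shared. With Villin WT 2 and Villin KO 1 both left out they were 151 on average, 343 in Villin, 123 in AhCre, 113 for the difference and 5377 between the WT groups. With each library left out they ranged from 2 to 757 on average, 73 to 1949 in Villin, 1 to 64 in AhCre, 0 to 415 for the difference and 8 to 3030 between the WT groups; the cause was not tested.

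The labels do not say whether replicate numbers pair the libraries. Deviations of libraries with the same number correlated at -0.11 in AhCre and 0.0610 and -0.22 in Villin. In a group of 2 libraries the deviations mirror each other, so these values cannot exclude a pairing. A replicate block gave 137 genes on average, 300 in Villin, 1 in AhCre and 0 for the difference by edgeR (2526 at an unadjusted p under 0.05). A block with crossed numbers in AhCre gave 48, 46, 1 and 0 (2754 at an unadjusted p under 0.05). Pcgf6 under the block was at -1.48 on average (adjusted p = 0.0726) and -2.09 in Villin (0.0560), and under the crossed block at -1.48 (0.126) and -2.09 (0.0773).

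Pcgf6 kept its direction in every setting. On average it was at -1.42 by voom (adjusted p = 0.0691), -1.43 with additive terms (0.0830) and -1.38 with Villin WT 2 and Villin KO 1 both left out (0.0661), and -1.55 to -1.31 with each library left out. In Villin it was at -1.96 by voom (0.214), -1.85 in the Villin libraries alone (0.136) and -1.90 with that pair left out (0.0679), and -2.13 to -1.76 with each library left out. In AhCre it passed by voom (-0.88, 0.0391) and in the AhCre libraries alone (-0.88, 0.0349), and was at -1.11 to -0.63 with each library left out. Of the results for named genes, 96 in most settings and 9 to 91 in the blocks, the stricter filter, the additive terms, the separate spread and the fits of 1 driver each, none reversed where it was run; of 96, 95 kept their call with size factors, 87 by DESeq2 and 70 by voom, and 40 without AhCre WT 1, 38 without AhCre WT 2 and 45 without Villin WT 1.

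With a correlation estimated from the data no list kept its call. Adjusted p on average were 0.0757 for tuft cell, 0.491 stem cell, 0.538 proliferation, 0.229 enterocyte, 0.0586 type 2, 0.215 fetal-like, 0.215 aryl hydrocarbon receptor, 0.776 myeloid, 0.225 stromal and 0.0757 stress genes. In Villin they were 0.188 tuft cell, 0.380 stem cell, 0.451 proliferation, 0.141 enterocyte, 0.102 type 2, 0.189 fetal-like, 0.440 myeloid, 0.140 stromal and 0.140 stress. In AhCre they were 0.153 tuft cell, 0.646 goblet, 0.646 Paneth, 0.646 enterocyte, 0.153 type 2, 0.690 myeloid and 0.459 stromal. For the difference they were 0.730 tuft cell, 0.730 Paneth, 0.430 stem cell, 0.730 proliferation, 0.237 enterocyte, 0.415 type 2, 0.418 myeloid, 0.2001 stromal and 0.398 stress.

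The preset correlation of 0.01 lay below those estimated for tuft cell genes, 0.872 on average, 0.893 in Villin and 0.793 in AhCre. For type 2 genes the estimates were 0.191, 0.165 and 0.193. Camera with the preset thus treats correlated genes as nearly independent and overstates the evidence for both lists. With the preset correlation and each library left out, the tuft cell and type 2 lists kept their calls. Adjusted p ranged from 8.16e-175 to 7.35e-69 on average, 5.20e-106 to 3.62e-26 in Villin and 5.14e-128 to 9.84e-56 in AhCre for tuft cell genes, and from 1.86e-29 to 6.87e-19, 7.10e-19 to 2.04e-11 and 9.30e-15 to 4.90e-09 for type 2 genes. The germline list ranged from 0.0380 to 0.816 on average, 0.231 to 0.974 in Villin and 0.0117 to 0.800 in AhCre. It was called on average without Villin WT 2 (0.0380), in AhCre without Villin WT 2 (0.0339) or Villin WT 3 (0.0117), and turned downward in Villin without Villin KO 2 (0.974). The correlation between drivers was -0.0654 by Spearman's rho, and Pearson's r was 0.0228 to 0.103 with each library left out.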

Other observations

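The gene list in this part was written, and the fit of the AhCre libraries alone was chosen for it, only after its leading genes had been seen.

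In the fit of the AhCre libraries alone Cbr3, a carbonyl reductase, rose by 4.58 (SE 0.21), the glutathione transferase Gsta3 by 3.04 (SE 0.20), Akr1b8 by 3.11 (SE 0.23) and the malic enzyme Me1 by 2.88 (SE 0.20). Of 25 tested genes known as NRF2-associated, 8 rose in that fit, among them Nqo1 (0.96), Gstm1, Akr1c13 and G6pdx, Gsta4 fell and the other members were not called, with a median of 0.45 and no test of the list. Outside that list the cytochromes Cyp2b10 (-2.08) and Cyp3a11 (-1.92) and the phosphatase Akp3 (-2.49) fell. In the fit of all libraries 0 of the 25 genes were called in AhCre by edgeR (4 rose adjusted over the list alone), and in Villin 3 rose and 1 fell. Cbr3 was at 139 and 114 CPM in AhCre KO against 5.81 and 4.85 in AhCre WT, and at 35.4 and 1.70 CPM in Villin KO against 12.8, 6.29 and 3.85 in Villin WT.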
